A study of Drosophila melanogaster with 2 samples.

How the data were processed

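Chromatin from whole Drosophila melanogaster embryos aged 0 to 24 hours was sonicated, with a fragment size range of 200 to 800 bp per the labels, and immunoprecipitated with an anti-GFP antibody in a line expressing Meics with a C-terminal GFP. There were 2 samples in 1 group, numbered 1 and 3 as biological replicates in the labels. The aligner, the peak caller and the IDR cutoff are not given in the sources used here. Per the labels, the authors deposited lists on the dm6 and dm3 builds. For each build there was a list of 30000 peaks and background regions for each replicate, a pooled list of 30000 regions, and a list thresholded by irreproducible discovery rate (IDR) from both replicates. The IDR-thresholded list was checked to hold the strongest regions of the pooled list, 7689 on dm6 and 7313 on dm3.

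The deposited signal value of each region (column 7 of the list) is the authors' own measure of enrichment. It was used to rank regions within a list, to describe single peaks, and in the correlation between the replicate lists. The deposited −log10 q-value reached its ceiling of 4.13 in 6671 of the 7689 peaks and was not used for ranking. The summit offset was added to the start of each region. The depth of the libraries is unknown, so no interval or floor that needs read counts is given. No control library was analysed here.

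All positions are in dm6 unless stated, counted from 1. Genes and TSSs came from the Ensembl annotation of BDGP release 6.54, on the same assembly as dm6, with 18164 genes on the 6 arms, of which 13945 are protein-coding. Sequence came from the RefSeq copy of that assembly. The dm3 lists were used only for counts and for the overlap and correlation of the replicates, and no coordinates were converted between builds.

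Each summit was put in the first class that applied: within 500 bp of any protein-coding TSS (promoter), 5′ UTR, coding exon, 3′ UTR, exon of a non-coding gene, intron, intergenic. Shares by chance came from 10000 circular rotations of the summits along each arm. Shares have Wilson 95% intervals. Gene lists, the X chromosome and divergent promoters were tested per gene with Fisher's exact test, two-sided. A gene counted as divergent when a coding TSS on the other strand lay upstream within 500 bp. P values were adjusted by Benjamini-Hochberg over the 24 lists, the 26 motifs, the 8-mers, the 7 annotation classes or the 6 arms. Protein-coding lists were compared with all other coding genes, and tRNA and snRNA genes with all other annotated genes. Across the lists, 28 symbols were not found in the annotation and were left out.

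Motifs and 8-mers were counted as present or absent on both strands in the 101 bp around each summit and in a window of the same length 500 bp to a side drawn at random, and compared with the exact McNemar test. A ratio of windows had 0.5 added to both counts. Replicates were compared by overlap of at least 1 bp between their 7689 strongest regions, with 1000 rotations, and by correlation of signal values over matched peaks, with 100000 permutations. For a replicate taken alone, the 7689 strongest regions of its own list stood in for the IDR-thresholded list; these are the settings without the other replicate.

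The gene lists, the motifs, the tests of the main comparisons and the rule for the genes named were fixed before the data were examined. What was chosen later is named where it is reported. The rule took the gene with the nearest coding TSS for the 25 strongest peaks, Meics itself, up to 4 members per list with the strongest peak within 500 bp, and the 5 strongest peaks with no TSS within 5000 bp. Members with near-identical copies (histone, tRNA and snRNA genes) were treated as uncertain. Alternatives were promoter windows of 200 and 1000 bp, the whole peak interval, TSSs of all genes, the upper part of the signal values, each replicate alone, shared promoters counted once, wider motif windows, promoters without a peak as motif background, stricter overlap rules, shorter lists and the dm3 lists. Leaving out 572 summits within 230 bp of a stronger one was added after the data were seen.

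The code was tested on simulated data. A planted promoter share of 30.0% came back as 30.0%, 4 of 4 planted gene lists and 0 of the rest were called, and a planted 8-mer ranked first of 32895. The planted summits were drawn from the same promoter windows that counted them, and the counts of the planted lists were drawn directly. These simulations therefore do not test the annotation or the assignment of summits to genes. A planted overlap of 59.6% of the replicates' regions came back as 61.7%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.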

Results

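The data are peak lists from chromatin immunoprecipitation and sequencing (ChIP-seq) of whole Drosophila melanogaster embryos collected between 0 and 24 hours and pooled over both sexes. The fly line carried Meics fused to GFP at its C-terminal end, and an anti-GFP antibody was used for the immunoprecipitation. Meics (Meiotic central spindle) is a zinc-finger protein named for its place on the spindle of dividing male germ cells. There was 1 group with 2 biological replicates, numbered 1 and 3 in the labels, so the comparisons are between peaks and the rest of the genome and between the replicates. The read depth of each library is unknown, and no control library was analysed here. Intervals on shares therefore cover counting error only, and neighbouring peaks and genes are not independent of each other. The deposited list thresholded by irreproducible discovery rate (IDR), a measure of how well ranks repeat between replicates, held 7689 peaks on the dm6 build. They were the strongest regions of the pooled list, and 6418 of them (83.5%) matched a region among the 7689 strongest of both replicates. Their median width was 460 bp, and all lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X.

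Most of the strongest peaks lay at promoters. The highest signal was at the promoter of CG17260 (FBgn0031498), with a signal value of 19876.5, which was 75.9 times the median of the list. Next came SMC2, a condensin subunit that compacts mitotic chromosomes (13242.9), tst, a helicase of the RNA-decay machinery (12485.2), MED17, a subunit of the Mediator complex (10838), and Golgin245, a Golgi tether (9947.97). Of the 25 strongest peaks, 18 had their summit within 500 bp of the transcription start site (TSS) of a protein-coding gene, and 6 lay in introns. All 25 ranked 28 or better in both replicate lists, each of which was ranked by its own signal value. The signal values come from the caller, and no difference in level was drawn between lists.

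In dm6 coordinates, the CG17260 peak spanned 2L from 3036930 to 3037888, with its summit at 3037409, 2 bp upstream of the TSS. The SMC2 peak spanned 2R from 14852346 to 14853311, with its summit 85 bp upstream of the TSS. The tst peak spanned 3R from 23772460 to 23773404, with its summit 42 bp upstream, and the MED17 peak spanned 3R from 18188432 to 18189351, with its summit 78 bp upstream. The other promoter peaks among the 25 were nearest to CG11504, CG42724, Ugalt, Noc1, Iml1, CG14100, mRpL4, Ptp99A, Mat1, BubR1, mRpL41, MFS12 and PNPase. BubR1 is a kinase of the spindle assembly checkpoint, Noc1 acts in ribosome biogenesis, and mRpL4 and mRpL41 encode proteins of the mitochondrial ribosome. The intronic peaks were nearest to CG11050, cbt, Trl, fok, CG32772 and Lk6. The summits nearest to cbt and fok lay outside these genes, in introns of other genes. Trl encodes the GAGA factor, and its intronic summit lay 1532 bp downstream of the nearest TSS. The remaining peak was in an exon of the non-coding gene lncRNA:CR44619, 5014 bp downstream of the nearest coding TSS, that of CG4004.

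The tagged gene itself had no IDR-thresholded summit at its promoter. Meics (FBgn0025874) lies on 3L from 13962658 to 13964702, and the nearest summit of the IDR-thresholded list was 7251 bp from its TSS. The list of replicate 1 held a region with its summit 117 bp from that TSS, at rank 3738 of 30000 by signal. In replicate 3 the nearest summit was 7257 bp away, and in the pooled list it was 7043 bp away. The line carries a tagged Meics transgene, and its effect on the values at this locus was not tested.

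Meics-GFP peaks were concentrated just upstream of genes and were nearly absent from coding sequence. Of the 7689 summits, 3307 (43.0%, Wilson 95% interval 41.9 to 44.1) were within 500 bp of a coding TSS, against 11.5% when the summits were rotated along each arm, a 3.75-fold difference. Coding exons outside promoters held 26 summits (0.338%) where rotation gave 13.9%. Introns held 38.7% of the summits, against 39.9% after rotation, and intergenic sequence held 14.4% against 27.9%. The 3′ UTRs held 1.16% against 4.52%. The rotations covered whole arms and left out no sequence where reads cannot be assigned to 1 place, so the rotated shares carry this limit. At promoters the summits sat upstream of the nearest TSS in 79.3% of the cases that were not at the TSS itself (interval 77.9 to 80.7), with a median position of -103 bp relative to it (exact binomial test, two-sided p = 1.15e-264).

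The rotation test, a permutation test with 10000 rotations, one-sided in the direction observed, gave p = 0.0001 for promoters, coding exons, 3′ UTRs and intergenic sequence, the smallest value it can give (adjusted p = 0.00017 over the 7 classes). Introns (adjusted permutation p = 0.1), 5′ UTRs (0.073) and exons of non-coding genes (0.097) did not pass. When each replicate's own 7689 strongest regions were used, the promoter share was 43.8% ± 0.929 (SD, n = 2) and the coding-exon share 0.338% ± 0.0552 (SD, n = 2).

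**Figure D1:**
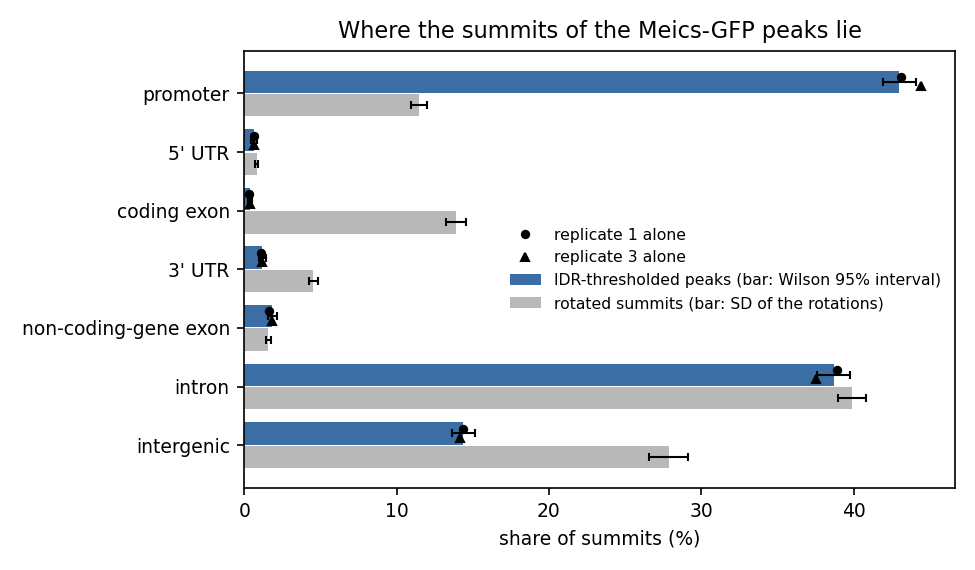
Share of summits in each annotation class (horizontal axis, percent) for the 7689 IDR-thresholded peaks (blue bars with Wilson 95% intervals), for each replicate's own list of the same length (points) and for rotated summits (grey bars with the SD over rotations). Promoters held 43.0% of the summits against 11.5% after rotation, and coding exons 0.338% against 13.9%.

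Promoter peaks were more frequent among the strong peaks than among the weak ones. The share of summits at promoters was 63.3% (interval 59.9 to 66.7) in the 769 strongest peaks and 31.5% (28.3 to 34.9) in the 768 weakest, while the intronic share went from 24.2% to 46.1%. Over all 7689 peaks, the correlation of signal rank with promoter class was 0.152 (permutation test with 100000 resamples, two-sided p = 1e-05, the smallest it can give). It is a correlation across peaks, which are not independent replicates.

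**Figure D2:**
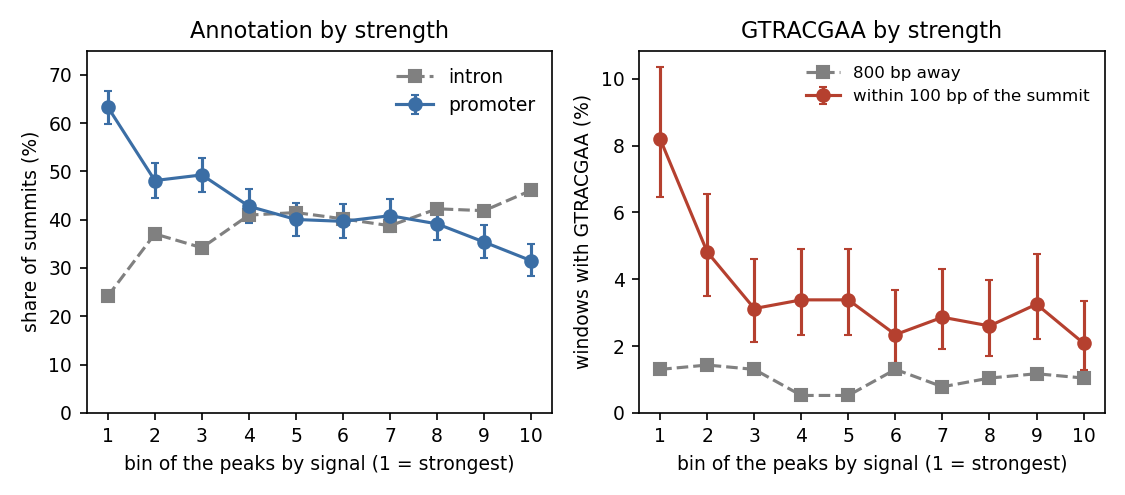
Left, share of summits at promoters and in introns (percent) for 10 equal bins of the IDR-thresholded peaks ordered by signal value, with bin 1 the strongest; right, percent of windows holding GTRACGAA within 100 bp of the summit and 800 bp away. Bars are Wilson 95% intervals. The promoter share goes from 63.3% to 31.5%, and the share with GTRACGAA from 8.19% to 2.08%. Bin 1 includes the 100 strongest peaks, where GTRACGAA was found.

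Of the 13945 coding genes on the 6 arms, 3645 (26.1%) had a summit within 500 bp of a TSS. Genes that share a promoter region with a gene on the other strand had one much more often. Among 3815 genes with a divergent coding TSS within 500 bp upstream, 45.1% (interval 43.5 to 46.6) had a summit, against 19.0% (18.3 to 19.8) of the other 10130 genes (Fisher's exact test, two-sided p = 2.57e-201).

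The X chromosome and the autosomes did not differ detectably. A summit was present at 26.5% of 2196 X-linked genes (interval 24.7 to 28.4) and at 26.1% of 11749 autosomal genes (25.3 to 26.9; Fisher's exact test, two-sided p = 0.672). The direction of this small difference turned in some settings. The X minus the autosomes was -1.24 percentage points in replicate 1 alone (Fisher's exact p = 0.234). With a 200 bp window it was -1.71 (Fisher's exact p = 0.0596), and with the upper part of the signal values -1.43 (0.103). On the small chromosome 4, 10 of 80 genes (12.5%, interval 6.93 to 21.5) had a summit, against 26.2% of the genes on the other arms (Fisher's exact test, adjusted p = 0.0277 over the 6 arms). The split by arm was made after the data were seen.

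Genes for cytosolic ribosomal proteins were occupied almost throughout. A summit lay within 500 bp of a TSS at 71 of 78 of them (91.0%, interval 82.6 to 95.6), against 25.8% of the other coding genes (Fisher's exact test, adjusted p = 2.08e-32 over 24 lists), and the share was 91.0% ± 1.81 (SD, n = 2) in the replicates taken singly. The strongest of these peaks were at RpS27 (signal value 2517.36), RpL7 (2409.66), RpL41 (1814) and RpL23A (1729.58). Genes of the central spindle and cytokinesis, the structure after which Meics is named, had a summit at 23 of 42 members (54.8%, interval 39.9 to 68.8, adjusted exact p = 0.000415). The strongest were at fws, sqh, which encodes the myosin regulatory light chain, chb, a microtubule plus-end protein, and tacc, a centrosomal protein. Insulator and architectural proteins had one at 14 of 27 genes (51.9%, adjusted exact p = 0.018), led by Chro, Cp190, Dref and Trl. A gene was counted when a summit lay near any of its TSSs. The tests of all lists do not adjust for the number of TSSs per gene, divergent promoters or expression.

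Another 4 lists were above the other genes, with smaller margins. They were the Polycomb and Trithorax groups (15 of 33, adjusted exact p = 0.0302; ph-p, brm, E(z) and Snr1), replication and cell cycle (19 of 43, 0.0294; BubR1, Dp, CycE and RnrS), heat shock (11 of 22, 0.0302; Hsp83, Hsp27, Hsc70-5 and Hsc70-4) and translation factors (21 of 53, 0.0461; eIF6, eIF4EHP, eEF1gamma and eIF1). With the strongest regions of replicate 3 alone, their adjusted exact p values were 0.0852, 0.0737, 0.0577 and 0.079, and with replicate 1 alone the heat shock and translation factor lists were at 0.0813 and 0.177. The Snr1 peak matched no region in the list of replicate 3.

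Several lists of tissue-specific genes held few peaks. Their expression in these embryos was not tested. Chemoreceptors had a summit at 1 of 179 genes (0.559%, Ir60e, adjusted exact p = 2.37e-21), cuticle proteins at 2 of 119 (Cpr67Fb and Cpr67Fa1, 2.11e-12), digestive enzymes and larval serum proteins at 1 of 49 (zetaTry, 4.22e-05), chorion and yolk proteins at 0 of 21 (0.00691) and testis-specific genes at 3 of 38 (bgcn, orb2 and bol, 0.0207). The chorion and yolk call held in 6 of 7 alternatives and the testis-specific call in 4 of 7. Genes of early zygotic expression and dorsoventral patterning were also below the rest (3 of 32: htl, T48 and ush, 0.0461), but not with replicate 1 alone (0.05004) or replicate 3 alone (0.117). This list kept its call in 0 of 7 alternatives. The multi-copy histone genes (0 of 111, 2.72e-14) and tRNA genes (26 of 290 against 22.4% of all other annotated genes, 1.56e-08) were below as well. Both are uncertain, because reads from near-identical copies cannot be assigned to 1 place.

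The other lists of developmental and tissue genes did not pass the test in either direction. Summits were present at 2 of 8 Hox genes (Dfd and Antp, adjusted exact p = 1), 5 of 32 segmentation genes (nkd, bcd, hb and cad the strongest, 0.341), 11 of 38 nervous system genes (elav, brp, fne and Fas2, 0.787), 10 of 29 muscle and mesoderm genes (Msp300, sls, tin and mbc, 0.418) and 8 of 26 genes of the Notch pathway (E(spl)m3-HLH, numb, aph-1 and neur, 0.786). The proteasome (11 of 32: Rpn5, Rpn3, Rpn11 and Rpn13 the strongest, 0.418), the mitochondrial respiratory chain (22 of 91: ND-ASHI, ND-MWFE, ND-42 and ND-51, 0.787), dosage compensation (2 of 10: Sxl and fru, 1) and snRNA genes (5 of 32, 0.66, uncertain because of similar copies) did not pass either. The dosage compensation list also held the sex-determination genes tra, dsx, ix and fru. A test that does not pass does not show that these lists are at the level of other genes.

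**Figure D3:**
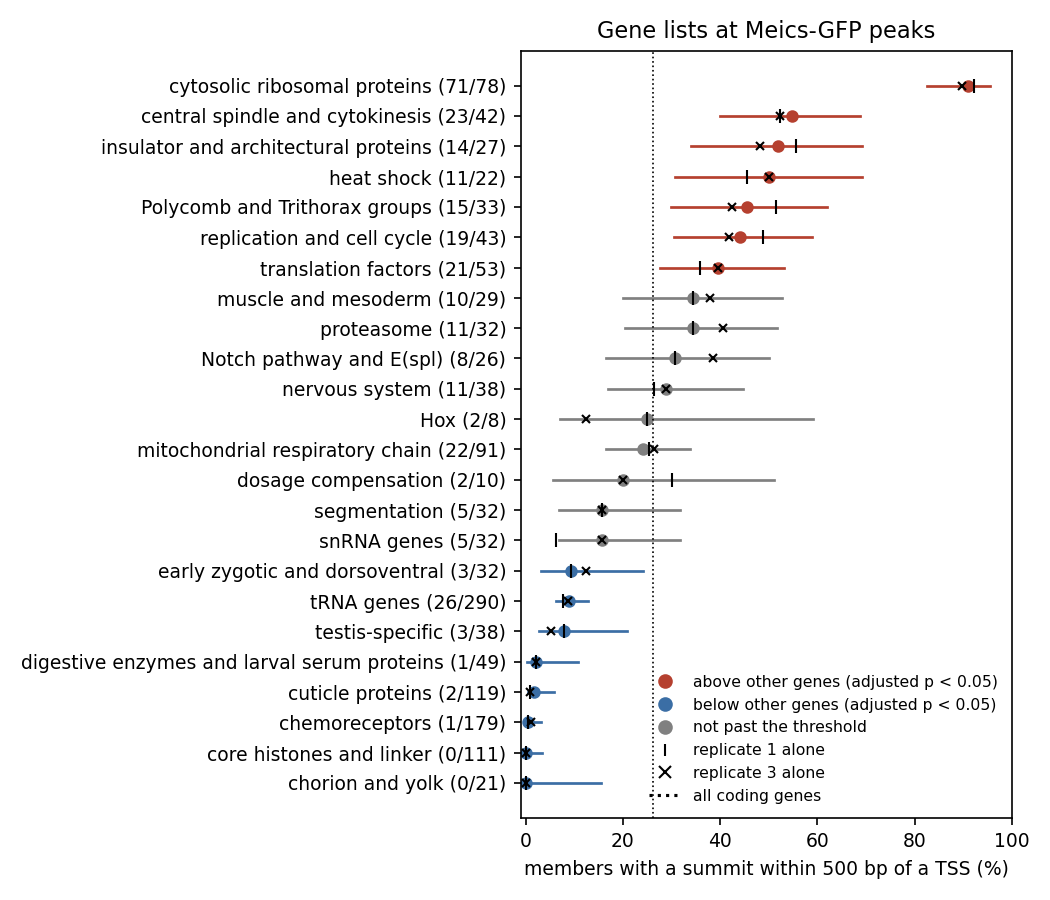
Share of each gene list's members with a summit within 500 bp of a TSS (horizontal axis, percent; circles, with Wilson 95% intervals as lines) and the same share from each replicate alone (black marks). Red and blue mark lists above or below the other genes at an adjusted p under 0.05. Ribosomal protein genes reach 91.0%, while chemoreceptors are at 0.559% and the dotted line for all coding genes is at 26.1%.

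Some strong peaks lay far from any annotated start. Of all summits, 1207 (15.7%) were more than 5000 bp from the TSS of any gene. The strongest of these, on 2L from 1638492 to 1639071 (signal value 2844.63), was intergenic, and the nearest coding TSS was that of chinmo. The next was intergenic on 2R from 13035117 to 13035567 (2627.2), followed by peaks in introns of simj (3L from 10682688 to 10683287, 2328.86) and CG32486 (3L from 3060611 to 3060987, 2080.68) and an intergenic peak on 3L from 10752498 to 10753018 (1982.76).

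The replicates shared most of their strong regions. Of the 7689 strongest regions of replicate 1, 6517 (84.8%, interval 83.9 to 85.5) overlapped 1 of the 7689 strongest of replicate 3 by at least 1 bp, against 4.23% after rotation (permutation test with 1000 rotations, one-sided p = 0.001, the smallest they can give). Among the IDR-thresholded peaks, 7600 (98.8%) matched a region in both lists of 30000, and over these the signal values of the replicates had a Spearman rho of 0.866 and a Pearson r of 0.915 on log10 values (permutation tests with 100000 resamples, p = 1e-05 for each, the smallest they can give). The IDR list had been chosen for reproducibility between the same replicates, so these correlations are across selected peaks.

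**Figure D4:**
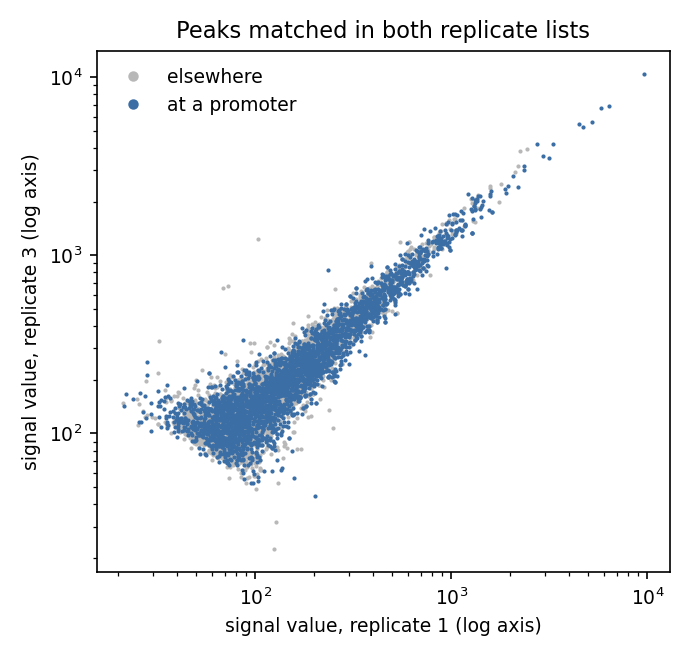
Signal value in replicate 1 (horizontal) and replicate 3 (vertical), both on log axes, for the 7600 IDR-thresholded peaks matched in both lists; blue points are peaks at promoters. The points form a single band, with a Spearman rho of 0.866, and the strongest peaks sit at its upper end.

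The DNA at the summits was rich in A and T and held some core promoter motifs more often than the flanks, and others less often. The GC content was 34.6% at the summits and 43.2% at 500 bp, and the motif tests do not correct for it, so the rise of TATAAA and the fall of CACGTG are not separated from base composition. TATCGATA, the element bound by DREF and BEAF-32, was within 50 bp of 1.46% of the summits and in 0.208% of windows 500 bp away (exact McNemar test, adjusted p = 5.53e-18 over 26 motifs). The M1BP motif GGTCACACT was at 0.689% against 0.104% (adjusted exact p = 1.55e-08), TATAAA at 22.1% against 10.5% (3.93e-82), and the CTCF motif at 2.03% against 1.16% (5.03e-05). Core promoter motifs 5, 6 and 7 and the shorter BEAF-32 site CGATA were enriched too, which made 8 motifs. The 7 depleted motifs were GAGA (1.31% against 2.9%), the CA repeat (1.46% against 3.81%), both CACGTG and CACATG E-boxes, DPE, TCT and the Pho motif. The initiator did not pass (8.73% against 9.34%, adjusted exact p = 0.252). In replicate 1 alone CACGTG and Pho were at an adjusted exact p of 0.0565, and in replicate 3 alone CACGTG was at 0.222. With the upper part of the signal values motif 5 was at 0.132. Promoters without a peak were also used instead of the flanks. All 7689 summits were set against them, although only 43.0% of the summits were at promoters. The values therefore do not compare promoters with and without a peak. The summits also differed from these promoters in their distance to a TSS. Calls made there, such as those of the initiator and DPE, are not separated from this difference in position. Against these promoters, 9 of the 15 motifs did not pass (Fisher's exact test). They were M1BP (0.689% against 0.624%, adjusted exact p = 0.833), CGATA (0.906), motif 5 (0.367), motif 6 (0.0946), GAGA (0.422), the CA repeat (0.664), CACATG (0.592), TCT (1) and Pho (0.353). TATCGATA was at 1.46% against 0.975% there (adjusted exact p = 0.0257), and TATAAA, CTCF and motif 7 were enriched and DPE and CACGTG depleted. Of the motifs without a call against the flanks, poly(A) (7.41% against 4.90%, adjusted exact p = 1.35e-09), GATA (0.0257) and AP-1 (0.0357) were enriched there and the initiator was depleted (8.73% against 10.4%, 0.00286).

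Among all 8-mers, 1696 of 32895 were enriched at the summits and 1953 depleted. Only 234 of the 1696 held 3 or more G or C bases. The test does not correct for the lower GC content at the summits, so these counts of 8-mers are not separated from base composition. The most significant that share no run of 6 bases were TTTAAAAA (445 summit windows against 146 flanking windows), AAAAATAT (505 against 199), ATTTTATA (301 against 84), AATAATAT (309 against 95) and ATCGATAG (127 against 13, adjusted exact p = 1.79e-21). GTGACGAA, picked after its values were seen, was in 130 summit windows against 16 flanking windows (adjusted exact p = 1.01e-20). With GTAACGAA it forms GTRACGAA, which was within 100 bp of 8.19% of the summits in the 769 strongest peaks and 2.08% in the 768 weakest. The 769 include the 100 strongest, where the word was found, and without these and 1 summit next to them it was 5.99% of 668.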

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

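The IDR-thresholded list on the dm3 build held 7 peaks outside the 6 chromosome arms, which the comparisons above do not use. Of these, 4 lay on the unplaced sequence Uextra, where the best ranked 2849 by signal, 2 on XHet and 1 on 3LHet. The dm6 lists held none outside the arms. No explanation was tested for these peaks.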

How the results depend on the processing

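The promoter share, the divergent promoters, the replicate overlap and rank correlation and the rise of the promoter share with peak strength kept their direction and their side of the threshold in every alternative run for them. The promoter share ran from 29.2% with a 200 bp window to 53.1% with a 1000 bp window, and the overlap from 70.4% to 91.0%. No paired analysis was possible because there is 1 group only. Leaving out summits within 230 bp of a stronger one was added after the data were seen. Values for gene lists are percentages of members with a summit minus that of other genes, in percentage points. Of the 24 lists, 3 of the 7 above other genes, 5 of the 8 below and all 9 that did not pass had the same call in all 7 alternatives. The upper part of the signal values left 3844 peaks by construction, and gave 8 called lists and 1046 enriched 8-mers, while windows of 100 bp to each side of the summit, in place of 50 bp, gave 2860. With those fewer peaks the difference was 13.8 for Polycomb and Trithorax groups, 13.8 for replication and cell cycle, 10.8 for heat shock, 11.8 for translation factors, -13.4 for early zygotic, -11.3 for testis-specific and -16.5 for chorion and yolk genes, none past the threshold; it turned for the X (-1.43) and for the lists not past the threshold of the nervous system (-3.36), proteasome (-4.02) and dosage compensation (3.49). A 200 bp window gave 11.7 for replication, -12.3 for early zygotic and -13.3 for testis-specific genes, which then did not pass, and turned the X (-1.71), nervous system (-5.42), muscle (-8.23), Notch (-3.18) and respiratory chain (1.23). A 1000 bp window gave 15.2 for Polycomb and Trithorax groups, 13.9 for replication, 11.3 for translation factors and -17.8 for early zygotic genes, all short of the threshold. With shared promoters counted once, early zygotic (-14.1) and testis-specific genes (-15.1) did not pass, and Hox (1.56) and the respiratory chain (2.96) turned. Without close summits, heat shock (19.5), translation factors (13.6) and early zygotic genes (-16.7) did not pass. From the settings without replicate 1 and without replicate 3, the range was -1.24 to 1.07 for the X, 15.6 to 25.4 for Polycomb and Trithorax groups, 15.1 to 22.7 for replication, 19.3 to 23.2 for heat shock, 9.70 to 12.8 for translation factors, -16.8 to -14.4 for early zygotic genes and -6.84 to 3.82 for dosage compensation. The cause was not tested for any of these changes. Of 130 alternatives for the 26 motifs, 86 kept the call and direction, and all 20 for the 8-mers named did. Calls gained against the flanks were Su(Hw) enriched with 100 bp windows (adjusted exact p = 0.0196), without replicate 3 (0.0411) and without replicate 1 (0.00803), poly(A) enriched with 100 bp windows (5.22e-05), fewer peaks (0.0249) and without replicate 3 (0.00014), the initiator (0.000871) and CRE (0.00558) depleted with fewer peaks, and Zelda (0.0267) and ETS (0.0151) depleted with 100 bp windows. For motifs without a call, the log2 ratio to the flanks or other promoters turned with 100 bp windows for the initiator (0.00638), AP-1 (-0.239) and Tramtrack (-0.131), with fewer peaks for ETS (0.0978), AP-1 (-0.15) and E2F (0.0888), and against promoters without a peak for CRE (0.737) and Tramtrack (-0.328). From the settings without each replicate it was -0.0863 to 0.0335 for the initiator, 0.0344 to 0.22 for ETS, -0.175 to 0.271 for CRE, -0.32 to 0 for AP-1, -0.0763 to 0.206 for GATA, 0 to 1.58 for the B box of RNA polymerase III genes and -0.0687 to 0.0229 for Tramtrack. Of the 74 genes named from the lists, 70 had a peak in each replicate alone and 44 with a 200 bp window. Because read depth is unknown, what it limits cannot be stated.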

Other observations

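The tests of gene groups, of GTRACGAA and of intronic against promoter summits in GC content were chosen after the results were seen, unlike the other test of GC content and those of divergent promoters. Genes for mitochondrial ribosomal proteins had a summit within 500 bp of a TSS at 36 of 73 members (49.3%, Wilson 95% interval 38.2 to 60.5), against 26.0% of the other coding genes (Fisher's exact test, adjusted p = 3.04e-05 over 4 groups, of which the olfactory receptors only repeat part of the chemoreceptor list), and at 49.3% in each replicate alone. The strongest were mRpL4, mRpL41 and mRpS10. Genes known only by a CG number had a summit at 18.4% of 6097 (against 32.2% of the others, adjusted exact p = 1.88e-76). Mediator subunits (9 of 25, adjusted exact p = 0.26) did not pass, although MED17 had one of the 25 strongest peaks.

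Among coding genes, 35 held 10 or more summits in their body, and these genes were picked after the data were seen. The most were in kirre (25 summits over 394149 bp), shn (21 over 58309 bp), sbb (19 over 79099 bp), CG1677 (19) and Tlk (17). Per 10 kb, kirre held 0.634 summits, CG1677 1.52, sbb 2.4, Tlk 2.44, shn 3.6 and tara 4.04, against 0.574 over the arms as a whole, so the count in kirre goes with its length. Replicate 1 alone gave 25 summits in kirre and 19 in shn, and replicate 3 alone 21 and 21. These genes were picked for their counts, so the counts are not a test.

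Of the 71 peaks at ribosomal protein genes, 88.7% were among the 3844 strongest of the 7689, with a median rank of 981. Of the 7689 strongest regions of replicate 1, 117 overlapped nothing in the pooled list of 30000, the best of them at rank 1091; replicate 3 had 100 such regions, the best at rank 1083.

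GTRACGAA was picked from the odd-ranked peaks of the 100 strongest and from sequences of the strongest peaks of both kinds, so its 18.0% (9 of 50) in the even-ranked ones is not a test. Of the 668 other summits of the 769 strongest whose windows do not touch those of the 100, 40 had it within 100 bp (5.99%, Wilson 95% interval 4.43 to 8.05), against 1.35% in windows 800 bp away; it was 6.04% without replicate 3 and 5.59% without replicate 1. There, 0% of 2000 words with the same letters in another order were at as many summits. The reordered words were not picked, whereas GTGACGAA was picked with its counts over all peaks in view, these 668 summits among them. This comparison therefore cannot decide on base composition. GTRACGAA was at 16 of 415 promoter summits (3.86%) and 1.13% of 12866 TSSs without a peak (Fisher's exact test, two-sided p = 4.8e-05). The former windows were centred on summits, which mostly lie upstream of TSSs, and the latter on TSSs. Promoter sequence in general is therefore not decided. Of the 768 weakest peaks, 2.08% had the word (Fisher's exact test, two-sided p = 0.00017), so it was not equally common near all peaks. Both comparisons use peaks whose values had been seen when the word was picked, so neither is an independent test. Signal at the same places in a control library was not tested here, and no biological explanation was tested.

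The GC content fell at the summits, from 43.2% at 500 bp to 34.6% in the central 51 bp, a fall of 8.62 percentage points (SE 0.17, 7689 peaks). Background regions, at ranks after 20000 of the 30000 in the pooled list, showed no such fall, with a ratio to the fall of the peaks of -0.0351, which argues against summit placement or a fragment bias independent of enrichment. Intronic summits fell as much as promoter summits, with a ratio of 1.04, which argues against promoter sequence as the cause at the intronic summits. It does not decide the cause at the promoter summits, because promoters without a peak were not compared. A bias that grows with enrichment stays open, and no biological explanation was tested.

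Divergent promoters held more summits than other promoters also per length of sequence. Merged promoter windows with divergent TSSs had 1.97 times as many summits per kb as the others (bootstrap 95% interval 1.84 to 2.1), which argues against window length alone. These windows hold TSSs on both strands, and summits per TSS were not compared. With genes whose TSSs lie within 500 bp counted once, 47.7% of the promoters with divergent TSSs and 18.9% of the others had a summit (Fisher's exact test, two-sided p = 3.1e-140). Promoters with divergent TSSs join TSSs of both strands, so their share would be higher also if every TSS were equally likely to have a summit. The comparison therefore cannot decide whether a neighbour was counted through a shared summit. Expression level was not tested, and no biological explanation was tested.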
